A study of Mus musculus with 29 samples.

How the data were processed

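DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads CpG dinucleotides in the CpG-rich part of the genome, in 29 mouse libraries of 15 groups. The embryonic stem cell (ESC) lines J-34, J-35 and J-37, all labelled male, were grown in serum with LIF (S/L) or in inhibitor media with LIF called 2i/L, a2i/L and PKCi/L. The labels give no composition for a2i/L and PKCi/L and name the single compounds used on J-34 only as PD and CHIR, which in this field are the usual short names of a Mek1/2 inhibitor and a Gsk3 inhibitor. Cells entered each medium at passage 4 and were collected at passage 10 (p10, 6 passages later) or passage 20 (p20, 16 passages later). Other 2i/L cultures were moved back to S/L after 16 passages and collected 3 or 10 passages later (p23 and p30). The remaining libraries came from male induced pluripotent stem cells without Mek1 and Mek2 (Mek1/2 double knockout, kept in S/L), from wild-type neonatal keratinocytes labelled female, and from keratinocytes labelled 2i/L and male, whose route from 2i/L culture the labels do not give. Per the labels' protocols, 12 barcoded reactions were pooled before bisulfite conversion and amplification, and the libraries were sequenced on an Illumina HiSeq2500.

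The authors deposited one list of CpGs per library. Per the submitters' processing notes, BSMAP 2.89 and the mouse build mm9 were used; filters, trimming and conversion rates are not given in the sources used here. In the deposited files each CpG carries its methylated reads over all its reads as one text field, and a score that equalled 1000 times that share, rounded down, at every CpG of all 29 files when checked. The files hold 1 value per CpG for both strands together, and nothing in them shows normalization or pooling of replicates. Coordinates are mm9 and are printed from the first to the last CpG of a region, counted from 1. A mouse gene table of another build (GRCm38.p6) was at hand but no mm9 annotation, so regions were not assigned to genes, exons or introns. The gene lists fixed beforehand (imprinted, germline, pluripotency, DNA methylation machinery, lineage, ERK target, keratinocyte and fibroblast genes) were therefore not used here, and no result exists for them.

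Groups, tests, thresholds, alternatives and the rule for the regions named were fixed before the data were examined; choices made later are stated as such. The planned minimum of 10 reads per CpG in each of the 29 libraries left 34895 autosomal CpGs, fewer than the 100000 required, and the minimum became 5 reads by the rule set beforehand. This left 337328 autosomal CpGs. Reads were summed over non-overlapping tiles of 1000 bp with at least 3 such CpGs, which gave 30888 autosomal tiles and 53 tiles on chromosome X, with a median of 95 reads and 5 CpGs per tile and library. Because a CpG had to be covered in all libraries, regions covered unevenly between sets of libraries are missing from every result.

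A count-based quasi-likelihood test was planned. The text field holds both counts, but it was recorded here under a unit other than counts, and count tools were kept for columns recorded as counts. The main test was therefore limma, which had been planned as the substitute, on log2((methylated + 1)/(unmethylated + 1)) per tile, fitted at once to the 21 libraries of the 8 replicated ESC groups with group as the single factor, two-sided, with Benjamini-Hochberg adjustment over autosomal tiles. A tile was called at an adjusted p under 0.05 and a difference of at least 20 percentage points between group means. A quasi-binomial logistic model with shrunken dispersion, chosen after the data were examined, was the second tool. The level of a library was its mean CpG methylation over the shared autosomal CpGs. Groups of 3 libraries were compared by exact two-sided permutation tests, where 3 against 3 cannot give a p below 0.1. Groups of 1 or 2 libraries were described without such a test. Tiles were also followed as sets: by CpG number, the tiles called lower in 2i/L p10 than in S/L p10, and 542 intermediate tiles that lay at 30 to 70% in the wild-type keratinocytes and in each S/L p10 library. Named regions are the 5 largest losses and the 5 largest gains among called tiles whose libraries did not overlap between the groups; those printed come from these lists unless stated otherwise.

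To study CpG-dense DNA, a broader set was added after the data were examined: CpGs with at least 1 read in every library, in tiles of at least 3 such CpGs and 20 reads in every library (47152 tiles). In this set, tiles of 10 or more CpGs are called dense here.

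The number of reads over CpGs ran from 8359802 in the wild-type keratinocytes to 22433006 in PKCi/L p20 of line J-35. A tile with the median depth carries a binomial error of several points in a single library. Wilson 95% intervals are given for shares of reads in unreplicated libraries. Reads were amplified without molecular identifiers, so intervals cover counting error only. Nothing in the labels says whether replicate lines came from separate animals, and p-values measure the spread between these libraries.

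The line names pair libraries across groups, since the same ESC line was grown in each medium. Deviations from group means were nevertheless almost unrelated in most pairs: over 30 pairs of libraries of the same line in different groups, r ranged from -0.0629 to 0.187 with a median of 0.00672. Of these pairs 20 lay above 0 and 2 above 0.1, and the 60 pairs of different lines had a median of -0.0012. The 2 pairs above 0.1 joined 2i/L p20 with p23 of J-34 (0.137) and of J-37 (0.187), while J-35 had 0.0258 there. Counting error in single tiles lowers r, so a low r does not show that a line deviates independently in each group. The fit with cell line as a block used 20 libraries. It left out 1 p30 library that is titled J-35 while its other labels say J-34; its group is not in conflict, and it is called the p30 library titled J-35 below.

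The labels give no sequencing batch. Which CpGs were covered split the libraries into 4 coverage sets (average-linkage clustering on a sample of 200000 CpGs, with the number of sets chosen after looking at the tree). Set 1 held 11 libraries: S/L, 2i/L, a2i/L and PKCi/L at p10, the CHIR and PD cultures and the double knockout. Set 2 held the 9 libraries of S/L p20, 2i/L p20 and p23. Set 3 held 8 libraries: a2i/L and PKCi/L at p20, p30 and the 2i/L keratinocytes. The wild-type keratinocytes stood alone in set 4. Comparisons inside a set are free of this difference. In comparisons across sets, the set and the group cannot be told apart.

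The test was tried on simulated data with the real depths, in which 200 of the 30888 tiles were changed. Levels and noise were taken from the S/L p20 libraries, and tiles were drawn independently. The real 2i/L p20 libraries spread more. Over the tiles called lower in 2i/L p10, the SD was 8.0 in 2i/L p20 and 0.761 in S/L p20. Far more tiles were also called in the real 2i/L comparisons than were changed here, so the rates below need not hold for them. For 2i/L p20 against S/L p20, limma recovered 62% of changes of 25 points and 100% of changes of 40 points with 0 false calls. For p23 against S/L p20 it recovered 48% and 98% with 1 false call, and for p30 against S/L p20 it recovered 28% and 94% with 4 false calls. The noise level of the simulation was revised once, from a median-based to a mean-based estimate.

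Alternatives were the second tool, the block, coverage minimums of 1, 10 and 20 reads, tiles of 500 bp, a 10-point and no minimum difference, a fit of the compared groups alone, shares of methylated reads in place of means over CpGs, an intermediate range of 40 to 60%, and leaving out each library in turn. Shares of methylated reads weight each CpG by its reads, so CpGs with very many reads can move them. CpGs with over 1000 reads held from 1.64% of reads (wild-type keratinocytes) to 7.26% (p23 of J-34). The software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and the data.table package at version 1.17.8.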

Results

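CpG methylation was measured by RRBS in 29 mouse libraries of 15 groups. S/L p10, 2i/L p10, S/L p20, 2i/L p20 and p23 (2i/L cells 3 passages after their return to S/L) had 3 libraries each, one per ESC line. The a2i/L p20, PKCi/L p20, p30 (10 passages after the return) and 2i/L keratinocyte groups had 2 libraries each. The double knockout, CHIR, PD, a2i/L p10, PKCi/L p10 and wild-type keratinocyte groups had 1 library each and so no replicates. The libraries held 8359802 to 22433006 reads over CpGs, and the lowest total was that of the wild-type keratinocytes.

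The first question was what 2i/L culture, which inhibits Mek1/2 and Gsk3, did to the ESC methylome. Cells in 2i/L had lost most of their CpG methylation by p10 and remained low at p20. The mean level was 21.9% ± 0.151 (SD, n = 3) in S/L p10 and 9.20% ± 0.124 (SD, n = 3) in 2i/L p10. At p20 it was 19.5% ± 0.250 (SD, n = 3) in S/L and 7.43% ± 2.37 (SD, n = 3) in 2i/L. The loss was spread over the methylated part of the measured genome: of 7464 tiles at 50% or more in S/L p20, 7425 were called lower in 2i/L p20 and 296 still lay at 50% or more. Of 8522 such tiles in S/L p10, 8375 were called lower in 2i/L p10 and 1332 still lay at 50% or more.

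Both global differences exceeded the spread between replicates, and the exact two-sided permutation p was 0.1 at each passage, the smallest that 3 against 3 can give. Of 30888 tiles, limma called 9902 lower and 0 higher in 2i/L at p10 and 8886 lower and 0 higher at p20. Beside these counts of 0, 14648 tiles at p10 and 13119 at p20 had an unadjusted p under 0.05, and the quasi-binomial model called 0 tiles higher at either passage. The 2 sets of lower tiles shared 8699 tiles, and the passages have no library in common. On chromosome 6, the tile from 71633469 to 71633613 (3 CpGs, at least 22 reads in each library compared) fell from 87.0% ± 8.54 in S/L p10 to 0.901% ± 1.56 in 2i/L p10 (SD, n = 3 each; limma adjusted p = 6.69e-13). On chromosome 2, the tile from 27994330 to 27994342 (3 CpGs, at least 33 reads) fell from 91.8% ± 4.68 in S/L p20 to 7.31% ± 7.0 in 2i/L p20 (SD, n = 3 each; limma adjusted p = 2.11e-11). That tile had returned to 75.1% at p23 and 83.3% at p30. The share of tiles called fell to 4.63% at p10 and 4.15% at p20 with a minimum of 10 reads per CpG, which keeps 3324 tiles, and rose to 60.6% and 57.2% with no minimum beyond 1 read.

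**Figure D1:**
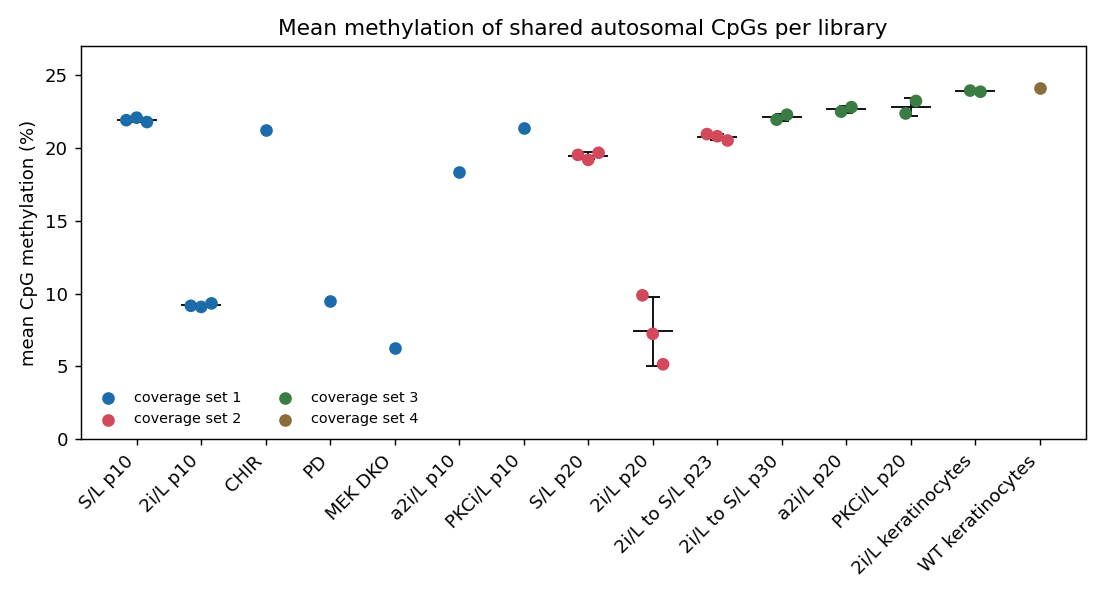
Mean methylation of the shared autosomal CpGs, in percent on the vertical axis, with 1 point per library coloured by coverage set, and horizontal lines and bars for the group mean and SD where a group has 2 or more libraries. The 2i/L libraries lie between 5.15% and 9.88%, the PD library at 9.47% and the double knockout at 6.26%, below all other libraries.

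Most of the tiles called lower were CpG-poor. A call needs a fall of at least 20 percentage points, which tiles with little methylation in S/L cannot show. The shares called therefore depend on the S/L level of each class. They do not show whether CpG density protects methylated DNA from the loss. Tiles of 3 to 9 CpGs had 31.8% ± 0.388 in S/L p20 and 12.1% ± 3.84 in 2i/L p20 (SD, n = 3 each), and 8820 of these 21709 tiles (40.6%) were called lower. Tiles of 10 to 29 CpGs had 1.56% ± 0.0168 in S/L p20 and 0.910% ± 0.0858 in 2i/L p20 (SD, n = 3 each), and 66 of 8085 (0.816%) were called lower. Tiles of 30 or more CpGs had 0.542% ± 0.0245 and 0.449% ± 0.0117 (SD, n = 3 each) over 1094 tiles, and the 8886 lower calls lay in the other classes. With shares of methylated reads, tiles of 30 or more CpGs had 4.03% in S/L p20 and 1.91% in 2i/L p20, a difference of -2.12 points, against -17.0 points in tiles of 3 to 9 CpGs. The exact two-sided permutation p was 0.1 in each class, the smallest possible.

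The second question was whether time in culture deepened the loss. In 2i/L the lines diverged: J-34 had 9.88% at p20, J-35 had 7.24% and J-37 had 5.15%, while at p10 the 3 lines lay between 9.09% and 9.33%. In S/L the level fell by 2.11 to 2.9 points from p10 to p20 within the lines. With shares of methylated reads it fell by 0.326 to 2.65 points within the lines (a mean of -1.18), and in tiles of 3 to 9 CpGs that share was 31.0% at p10 and 31.2% at p20. On chromosome 12, the tile from 55726412 to 55726437, still at 90.1% ± 3.10 in 2i/L p10, had 42.7% ± 12.6 in 2i/L p20 (SD, n = 3 each; limma adjusted p = 0.00304). In S/L the tile on chromosome 9 from 110301020 to 110301044 fell from 73.1% ± 25.8 at p10 to 25.2% ± 6.78 at p20 (SD, n = 3 each; limma adjusted p = 0.00539), and the tile on chromosome 16 from 61056181 to 61056202 rose from 3.22% ± 0.591 to 25.0% ± 5.96 (SD, n = 3 each; limma adjusted p = 6.96e-06). The level of the chromosome 16 tile went with the coverage set in the ESC libraries. It had 12.7% in 2i/L p20 and 26.9% at p23 (set 2). In set 3 it had 60.3% in a2i/L p20, 61.4% in PKCi/L p20 and 63.2% at p30.

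The exact two-sided permutation p for the global level was 0.4 in 2i/L and 0.1 in S/L, and with shares of methylated reads it was 0.2 in S/L. Between p10 and p20, limma called 21 tiles lower and 0 higher in 2i/L, with 3345 at an unadjusted p under 0.05, and 83 lower and 2 higher in S/L; the quasi-binomial model called 175 lower and 1 higher in 2i/L and 477 lower and 3 higher in S/L. Without 2i/L p20 of line J-34, the 2i/L comparison called 356 tiles lower, and without any other single library of it 6 to 11; in S/L, leaving out any 1 of the 6 libraries left 15 to 37 lower. The effect of 2i/L at p20 less its effect at p10, tested as an interaction, was called at 38 tiles, all with a smaller loss at p20, and at 0 tiles in the other direction (limma; 2860 at an unadjusted p under 0.05; 9 and 0 by the quasi-binomial model). Without 2i/L p20 of line J-37 this was 106 and 1 tiles, without single S/L libraries other than S/L p20 of J-35 6 to 16, and with the 4 groups fitted alone 1. The p10 and p20 libraries lie in different coverage sets, so set and passage cannot be told apart in these comparisons.

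Single libraries were compared to see which inhibitor went with the low level, and whether cells without Mek1 and Mek2 had it as well. PD alone gave a methylome close in level to 2i/L, at 9.47%, and CHIR alone gave one close to S/L, at 21.3%. The double knockout cells had the lowest level of the libraries in coverage set 1, at 6.26%, although they were kept in S/L. They are induced pluripotent stem cells, and no such cells with Mek1 and Mek2 were measured. Their genotype therefore cannot be told apart from their cell origin. In the 9902 tiles called lower in 2i/L p10, the share of methylated reads was 29.4% (Wilson 95% interval 29.3 to 29.5%) with PD, 69.9% (69.8 to 70.1%) with CHIR and 18.9% (18.84 to 19.01%) in the double knockout. In the libraries that defined this set, the share was 72.1% in S/L p10 and 28.6% in 2i/L p10. On chromosome 6, the tile from 71633469 to 71633613 had 23.8% with PD, 88.1% with CHIR and 7.32% in the double knockout. These groups have 1 library each, so no test was made, and the intervals cover counting error only; all these libraries share coverage set 1 with S/L p10 and 2i/L p10.

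The third question was whether the other inhibitor media changed methylation as 2i/L did. They did not lower it to the level of 2i/L at either passage. At p20 the mean level was 22.6% ± 0.218 in a2i/L and 22.8% ± 0.607 in PKCi/L (SD, n = 2 each), against 7.43% in 2i/L. At p10 the single libraries had 18.4% in a2i/L (J-34) and 21.3% in PKCi/L (J-35). In the tiles called lower in 2i/L p10, the share of methylated reads was 59.8% (Wilson 95% interval 59.7 to 59.9%) in a2i/L p10 and 68.8% (68.7 to 68.9%) in PKCi/L p10.

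Against 2i/L p20, limma called 10113 tiles higher and 1 lower in a2i/L and 10079 higher and 1 lower in PKCi/L. On chromosome 1, the tile from 36030826 to 36030955 had 96.8% ± 1.73 in a2i/L (SD, n = 2) and 8.73% ± 6.01 in 2i/L p20 (SD, n = 3; limma adjusted p = 5.8e-13). The 1 lower tile was the same in both, on chromosome 10 from 11211899 to 11211974 (6 CpGs), at 11.3% ± 6.15 in a2i/L, 5.88% ± 1.49 in PKCi/L (SD, n = 2 each) and 32.6% ± 9.03 in 2i/L p20 (SD, n = 3). It had 87.9% ± 2.15 in S/L p20 and 71.6% ± 7.80 at p23 (SD, n = 3 each) but 10.4% ± 1.99 at p30 (SD, n = 2), so its low level went with coverage set 3 in the ESC libraries.

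Against S/L p20, a2i/L was higher at 1700 tiles and lower at 50, and PKCi/L was higher at 1352 and lower at 19 (limma). On chromosome 13, the tile from 51324370 to 51324502 had 86.8% ± 4.89 in a2i/L, 85.55% ± 5.28 in PKCi/L (SD, n = 2 each) and 10.9% ± 0.173 in S/L p20 (SD, n = 3; limma adjusted p = 5.76e-07 and 1.5e-06). On chromosome 7, the tile from 134379305 to 134379465 was lower in a2i/L p20, at 4.67% ± 1.32 (SD, n = 2) against 54.8% ± 3.84 in S/L p20 (SD, n = 3), and had 4.76% in PKCi/L p20, 6.16% in 2i/L p20, 31.5% at p23 and 42.8% at p30. Over the 1700 tiles higher in a2i/L the mean was 71.2% in a2i/L, 63.0% in PKCi/L, 39.0% in S/L p20 and 53.8% in S/L p10, and at 426 of them a2i/L lay no more than 10 points above S/L p10. The p30 cells, in S/L but in the same coverage set as a2i/L p20, had 61.6%, and the p23 cells had 52.0%. Inside coverage set 1, the global level at p10 was 18.4% in a2i/L and 21.3% in PKCi/L, below the 21.9% of S/L p10. The a2i/L count was 1032 higher and 25 lower without line J-34 and 821 and 36 without J-35; the PKCi/L count was 856 and 10 without J-34 and 516 and 17 without J-35. The global level turned from 3.19 points above S/L p20 to -2.60 in a2i/L and from 3.34 to -4.54 in PKCi/L when shares of methylated reads replaced means over CpGs, and these groups lie in another coverage set than S/L p20.

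At p20 few tiles were called between the 2 media, in a comparison of 2 against 2 libraries whose recovery of changes was not simulated. The single p10 libraries, from different lines, stood further apart in global level, at 18.4% in a2i/L and 21.3% in PKCi/L. PKCi/L p20 was higher than a2i/L p20 at 53 tiles and lower at 33 (limma), within coverage set 3. On chromosome 19, the tile from 7345608 to 7345728 had 21.4% ± 9.32 in PKCi/L and 76.9% ± 2.68 in a2i/L (SD, n = 2 each; limma adjusted p = 0.00381), and the single p10 libraries had 20% and 52.8%. On chromosome 10, the tile from 119869819 to 119869906 had 72.9% ± 1.91 in PKCi/L and 16.2% ± 12.4 in a2i/L (SD, n = 2 each; limma adjusted p = 0.00159), and the p10 libraries had 51.5% and 2.97%. Leaving out any 1 of the 4 libraries left 6 to 21 tiles higher and 5 to 10 lower, and the quasi-binomial model called 0.819% of tiles against 0.278% by limma.

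**Figure D2:**
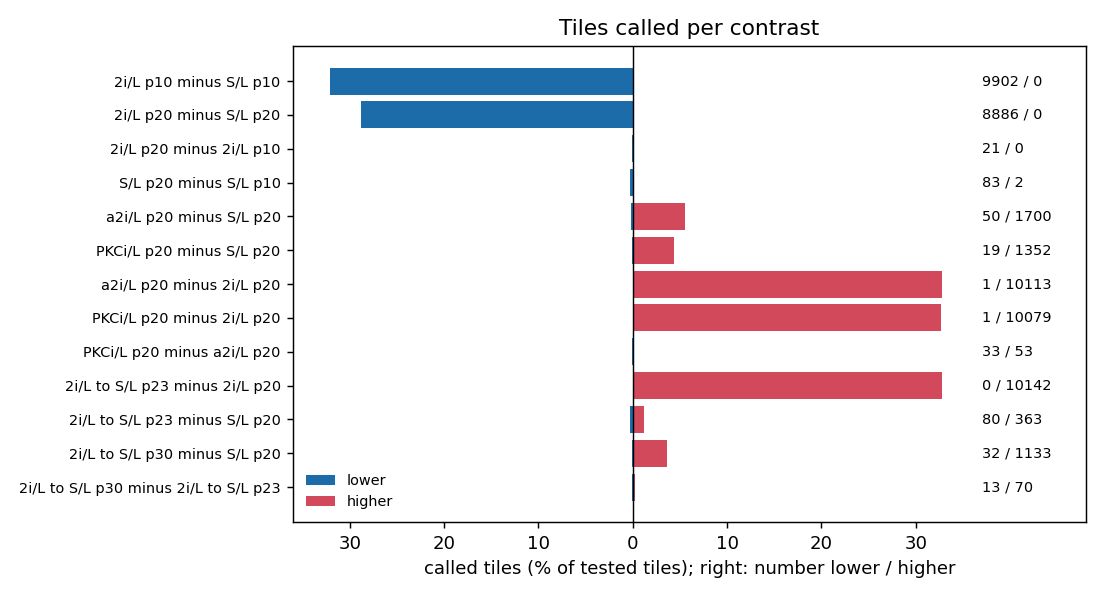
Tiles called by limma in each contrast, in percent of the 30888 tested on the horizontal axis, with lower calls to the left of 0 and higher calls to the right and the 2 counts printed beside each bar. The contrasts that set 2i/L against S/L, a2i/L, PKCi/L or returned cells hold 28.8% to 32.8% of the tiles, and all others shown 5.67% or fewer.

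The fourth question was whether methylation came back when cells left 2i/L. Within 3 passages in S/L the bulk of it had. The mean level was 20.8% ± 0.223 at p23 (SD, n = 3) and 22.1% ± 0.241 at p30 (SD, n = 2), against 7.43% in 2i/L p20 and 19.5% in S/L p20. Of the 9902 tiles called lower in 2i/L p10, 66 (0.667%) were lower than S/L p20 at p23 and 21 (0.212%) at p30, while 258 and 823 were higher. The mean over this set was 65.0% in S/L p20, 23.6% ± 8.0 in 2i/L p20, 68.8% ± 0.846 at p23 (SD, n = 3 each) and 73.0% ± 0.564 at p30 (SD, n = 2). The lower counts were 17 to 37 at p23 without any 1 S/L p20 or p23 library, and at p30 13 and 10 without S/L p20 of J-34 or J-35 and 10 and 2 without the p30 library titled J-35 or that of J-37.

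Against 2i/L p20, 10142 tiles were higher at p23 and 0 lower (limma; 15022 at an unadjusted p under 0.05; 10144 and 0 by the quasi-binomial model), and the exact two-sided permutation p for the global level was 0.1, the smallest possible. On chromosome 3, the tile from 89676324 to 89676366 rose from 6.98% ± 1.96 in 2i/L p20 to 87.9% ± 2.85 at p23 (SD, n = 3 each; limma adjusted p = 4.3e-12). This comparison lies within coverage set 2.

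Against S/L p20, the returned cells differed at few tiles and mostly upward. At p23, 363 tiles were higher and 80 lower, within coverage set 2 (limma). On chromosome 2, the tile from 129341683 to 129341898 had 79.2% ± 4.39 at p23 and 32.9% ± 8.26 in S/L p20 (SD, n = 3 each; limma adjusted p = 0.000505), and S/L p10 had 65.0%. Over the 363 higher tiles the mean was 51.7% at p23, 24.0% in S/L p20 and 40.3% in S/L p10. On chromosome 7, the tile from 134755129 to 134755275 had 35.1% ± 8.21 at p23 and 84.7% ± 3.34 in S/L p20 (SD, n = 3 each; limma adjusted p = 0.00138), after 19.4% in 2i/L p20. Over the 80 lower tiles the mean was 76.9% in S/L p20, 21.3% in 2i/L p20, 46.9% at p23 and 67.1% at p30. The global level was 1.30 points above S/L p20 (exact two-sided permutation p = 0.1). It was -1.01 points from it with a minimum of 20 reads per CpG, which keeps only 563 of the 337328 autosomal CpGs. Leaving out any 1 of the 6 libraries left 172 to 223 tiles higher and 20 to 45 lower.

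At p30, 1133 tiles were higher than in S/L p20 and 32 lower (limma), or 750 and 17 without the p30 library titled J-35, and 676 and 13 with cell line as a block in addition. On chromosome 18, the tile from 47127927 to 47127950 had 79.0% ± 17.4 at p30 (SD, n = 2) and 10.3% ± 1.72 in S/L p20 (SD, n = 3; limma adjusted p = 3.88e-07), against 24.3% in S/L p10. On chromosome 2, the tile from 157385320 to 157385339 had 55.5% ± 8.36 in S/L p20 and stayed low after the return, with 9.65% ± 8.64 at p23 (SD, n = 3 each) and 6.94% ± 9.82 at p30 (SD, n = 2; limma adjusted p = 0.00154 and 0.00206). From p23 to p30, 70 tiles rose and 13 fell, or 26 and 4 without that library, and 36 and 2 with the block in addition. On chromosome 5, the tile from 110861009 to 110861020 rose from 21.8% ± 1.93 (SD, n = 3) to 85.0% ± 4.94 (SD, n = 2; limma adjusted p = 2.63e-05). Without the p30 library of J-37 the comparison with S/L p20 called 384 tiles higher and 4 lower, and leaving out any 1 of the 5 libraries from p30 against p23 left 25 to 35 higher and 4 to 8 lower. The p30 libraries lie in another coverage set than S/L p20 and p23, and with shares of methylated reads the global level at p30 was -1.36 points from S/L p20 in place of 2.65.

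Intermediate tiles, a set in which regions with a single methylated allele would lie, were followed separately. They fell with the rest of the genome in 2i/L and came back as a group. The mean over the 542 tiles was 38.9% ± 0.833 in S/L p20, 12.4% ± 3.69 in 2i/L p20, 47.4% ± 0.461 at p23 (SD, n = 3 each) and 50.5% ± 1.03 at p30 (SD, n = 2). It was 52.1% ± 1.24 in a2i/L p20 and 52.8% ± 2.23 in PKCi/L p20 (SD, n = 2 each), and 13.5% with PD, 45.4% with CHIR and 9.23% in the double knockout. The single p10 libraries had 33.3% in a2i/L and 45.5% in PKCi/L, against 50.9% in S/L p10, which helped to define the set. In 2i/L p20, 385 tiles were lower than in S/L p20 (limma); 31 were higher and 9 lower at p23, and 85 and 4 at p30. The exact two-sided permutation p was 0.1 for 2i/L p20 and for p23 against S/L p20, the smallest possible. With a minimum of 10 reads per CpG, which leaves 10 intermediate tiles, the means at p23 and p30 lay -0.137 and -2.08 points from S/L p20 in place of 8.53 and 11.6.

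A small group of CpG-dense tiles was still lower at p23, a group defined after the data were examined. Of 18212 dense tiles, 961 were called lower in 2i/L p20 than in S/L p20, and 10 of these were also called lower at p23. The other 951 had regained a median of 107% of their loss at p23 (quartiles 97.7 and 125%). Of the 10 tiles, 7 lay at 30 to 70% in the wild-type keratinocytes. These are on chromosome 2 from 157386010 to 157386214, from 174124504 to 174124998 and from 174125015 to 174125971, on chromosome 10 from 12810429 to 12810995, and on chromosome 11 from 11925612 to 11925947, from 11926175 to 11926884 and from 22872010 to 22872993. Their mean was 44.9% ± 3.03 in S/L p10, 38.5% ± 0.177 in S/L p20, 19.7% ± 1.30 in 2i/L p10, 8.56% ± 7.64 in 2i/L p20, 9.36% ± 4.36 at p23 (SD, n = 3 each) and 11.4% ± 6.71 at p30 (SD, n = 2). It was 7.45% with PD, 0.651% in the double knockout and 40.2% with CHIR. On chromosome 11, the tile from 22872010 to 22872993 (33 CpGs, at least 170 reads in every library) had 34.3% ± 3.51 in S/L p20, 7.61% ± 6.52 in 2i/L p20, 7.49% ± 4.91 at p23 (SD, n = 3 each) and 6.58% ± 6.48 at p30 (SD, n = 2). At p30, 5 of the 7 tiles were called lower than in S/L p20; from 174124504 to 174124998 and from 174125015 to 174125971 the differences were -17.5 and -15.3 points (limma adjusted p = 0.0534 and 0.262).

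The other 3 tiles stood higher at p30 than at p23 and were not called lower there (limma adjusted p = 0.755, 0.385 and 0.237). They are on chromosome 7 from 7230392 to 7230962 and from 88295180 to 88295737, and on chromosome 13 from 13018091 to 13018498, with a mean of 72.5% in S/L p20, 20.6% in 2i/L p20, 50.02% at p23 and 64.8% at p30. The p30 and S/L p10 libraries did not define the group: at p30, 7 of the 10 tiles lay 20 points or more below S/L p10, against 16 of the other 951. The count of 10 was 12 by the quasi-binomial model and 6 in the tiles of the 5-read minimum. Without 1 library it fell to 5 (S/L p20 of J-34, or p23 of J-35), 6 (S/L p20 of J-35) or 3 (p23 of J-37).

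**Figure D3:**
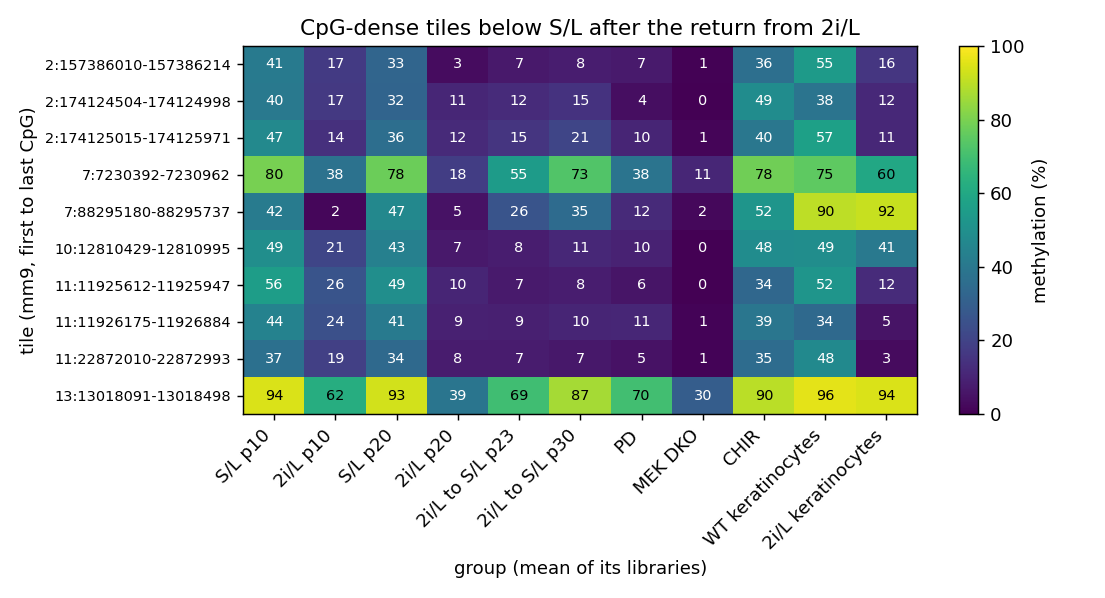
Methylation of the 10 CpG-dense tiles called lower in 2i/L p20 and at p23 than in S/L p20, with 1 line of squares per tile (mm9 position on the vertical axis), groups on the horizontal axis and the group mean in percent as colour and printed value. The 7 tiles at 30 to 70% in the wild-type keratinocytes average 9.36% at p23 and 11.4% at p30, and the 3 others have 50.02% and 64.8%.

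Keratinocytes labelled 2i/L were compared with wild-type keratinocytes. The labels do not give the route of the former from 2i/L culture, so they cannot be taken as descendants of these ESC lines. The level was 23.9% ± 0.0554 in the 2i/L keratinocytes (SD, n = 2) and 24.1% in the wild-type library. Both lay somewhat above S/L cells, which had 21.9% at p10 and 19.5% at p20, and far above 2i/L cells. In the tiles called lower in 2i/L p10, the share of methylated reads was 73.8% and 73.2% in the 2i/L keratinocytes and 74.0% (Wilson 95% interval 73.8 to 74.1%) in the wild-type library. The 7 dense tiles had 14.2% ± 2.16 in the 2i/L keratinocytes (SD, n = 2) and 47.6% in the wild-type library, but that library was used to choose them. The other 3 of the 10 had 82.0% and 87.0%, and all 10 had 34.6% ± 1.67 (SD, n = 2) and 59.4%. With shares of methylated reads, tiles of 30 or more CpGs had 10.1% ± 0.191 in the 2i/L keratinocytes (SD, n = 2) and 1.19% in the wild-type library, against 0.920% and 0.887% as means over tiles. On chromosome 11, the tile from 22872010 to 22872993 had 2.37% and 3.24% in the 2i/L keratinocytes and 47.6% (Wilson 95% interval 40.3 to 55.1%, 170 reads) in the wild-type library. On chromosome 10, the tile from 12810429 to 12810995 was closer, at 37.8% and 43.4% against 48.9% (42.4 to 55.4%).

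Both 2i/L keratinocyte libraries lay 20 points or more below the wild-type library at 6 of the 10 tiles and at 11 of the other 951 lost dense tiles (Fisher's exact test over tiles, two-sided, p = 2.32e-09). Among tiles at 30 to 70% in the wild-type library this was 6 of 7 and 5 of 153 (Fisher's exact test over tiles, two-sided, p = 1.48e-07). Tiles are not replicates, neighbouring tiles are not independent, and there was 1 wild-type library, female and in its own coverage set.

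The sex labels were checked on the sex chromosomes. The wild-type keratinocytes, labelled female, had 2.08% of reads on chromosome X, and all libraries labelled male had between 0.929% and 1.13%. The wild-type keratinocytes also had the highest level over the 53 tiles of chromosome X, at 37.6%, against 14.7% and 15.1% in the 2i/L keratinocytes. In ESCs these tiles had 10.8% ± 0.391 in S/L p20, 4.63% ± 1.47 in 2i/L p20 and 10.3% ± 0.900 at p23 (SD, n = 3 each).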

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

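Of the tests in this part, the exchange of passage labels was chosen only after the result was seen.

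The effect of 2i/L differed between the passages at 38 tiles, which a test of the difference itself picked out. At all 38 the loss in 2i/L relative to S/L was smaller at p20 than at p10. Yet 0 tiles were called higher in 2i/L p20 than in 2i/L p10. Over all tiles the mean difference of p20 from p10 was -1.89 points in 2i/L and -3.19 in S/L. A smaller loss is therefore not a called rise of methylation in 2i/L. Exchanging the medium labels within each passage gave as many tiles in 14 of 100 splits drawn, with 10904 in the highest other. By that test chance is not excluded; splits that mirror the labels of 1 passage alone add the medium effects of both passages, so they show the medium effect and not the difference between passages. Exchanging the passage labels within each medium gave as many tiles in 3 of 100 splits, with 197 in the highest other, a share under 0.05. These splits also mix the passage effect shared by both media into the groups. The share therefore does not test the difference between passages alone. The passages lie in different coverage sets, and the count was 9 by the quasi-binomial model and 1 with the 4 groups fitted alone.

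For the comparisons of 3 against 3 libraries, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split, the 1 that gave as many tiles in each case, called 9902 tiles for 2i/L p10 against S/L p10, and the highest other called 0. For 2i/L p20 against S/L p20 these were 8886 and 0, for 2i/L p20 against 2i/L p10 21 and 2, and for S/L p20 against S/L p10 83 lower with 2 higher and 1. For p23 they were 10142 and 0 against 2i/L p20, and 363 higher with 80 lower and 0 against S/L p20.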

How the results depend on the processing

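Of the tests here, the quasi-binomial model, the broad tiles and the alternatives for the dense tiles were chosen only after the results were seen. The loss of methylation in 2i/L at both passages, and its recovery at p23, kept their direction under every alternative run. Of all values under an alternative, 225 stayed close to the main value, 141 moved and 9 changed sign. The planned count-based quasi-likelihood test was not run. Of the coverage minimums, 10 reads per CpG leave 3324 tiles and 20 reads leave 40, on which shares rest on few tiles, and 1 read leaves 83797, so the tested genome itself changes. For other changes the cause was not tested.

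The fit with cell line as a replicate block also left out the p30 library titled J-35. It called 2.23% of tiles for p30 against S/L p20, against 2.48% without that library and no block and 3.77% with all libraries, and for p30 against p23 0.123%, against 0.0971% and 0.269%. No other comparison changed by over 1.5 times in that fit.

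With the quasi-binomial model the share of tiles called was 0.570% for 2i/L p20 against 2i/L p10, 1.55% for S/L p20 against S/L p10, 0.0291% for the interaction, 0.819% for PKCi/L p20 against a2i/L p20, 2.47% for p23 against S/L p20 and 0.615% for p30 against p23.

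With at least 10 reads per CpG the share called was 4.63% for 2i/L p10 and 4.15% for 2i/L p20 against S/L, 0.120% for 2i/L p20 against 2i/L p10, 0.0301% for S/L p20 against S/L p10, and 0 for the interaction and for PKCi/L against a2i/L. It was 0.812% for a2i/L and 0.632% for PKCi/L against S/L p20, 4.63% and 4.69% against 2i/L p20, 4.87% for p23 against 2i/L p20, 0.181% for p23 and 0.481% for p30 against S/L p20, and 0.120% for p30 against p23. Of the tiles lower in 2i/L p10, 1.95% were lower at p23 and 1.95% at p30. Differences from S/L in global level, in points, were -10.5 for 2i/L p10, -9.55 for 2i/L p20, 2.51 for a2i/L, 2.56 for PKCi/L and 2.07 for p30. Intermediate tiles differed from S/L p20 by -30.5 in 2i/L p20, -0.137 at p23 and -2.08 at p30, the last 2 with a changed sign.

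With at least 20 reads the share called was 7.5% for 2i/L p20 against 2i/L p10 and for p30 against S/L p20, and 2.5% for S/L p20 against S/L p10, the interaction, a2i/L, PKCi/L and p23 against S/L p20 and p30 against p23. It was 0 for PKCi/L against a2i/L. Of the tiles lower in 2i/L p10, 0% were lower at p23 and 23.1% at p30, but these tiles are only a part of the 40 left. Global differences from S/L, here over only 563 autosomal CpGs, were -10.9 for 2i/L p10, -13.9 for 2i/L p20, 2.82 for a2i/L and 0.259 for p30. They changed sign to -0.144 for PKCi/L and -1.01 for p23. The 3 intermediate tiles left differed by -37.5 in 2i/L p20 and, with a changed sign, by -18.9 at p23 and -11.3 at p30.

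With no minimum beyond 1 read the share called was 60.6% for 2i/L p10 and 57.2% for 2i/L p20 against S/L, 0.163% for 2i/L p20 against 2i/L p10, 0.0501% for the interaction, 7.15% for PKCi/L against S/L p20, 62.4% for a2i/L, 62.5% for PKCi/L and 62.3% for p23 against 2i/L p20, and 0.461% for p30 against p23. Global differences from S/L were -17.7 for 2i/L p10, -17.4 for 2i/L p20, 4.36 for a2i/L, 4.57 for PKCi/L and 3.49 for p30, and intermediate tiles differed by 9.71 at p23 and 13.9 at p30.

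Tiles of 500 bp gave 0.171% for S/L p20 against S/L p10, 0.0581% for the interaction and 0.183% for PKCi/L against a2i/L. A 10-point difference gave 2.16% for p23 against S/L p20. No minimum difference gave 0.146% for 2i/L p20 against 2i/L p10, 8.86% for a2i/L, 7.23% for PKCi/L, 2.69% for p23 and 5.97% for p30 against S/L p20, and 0.473% for p30 against p23. Broad tiles gave 2.42% for p23 and 6.03% for p30 against S/L p20. Fits of the compared groups alone gave 0.01295% for 2i/L p20 against 2i/L p10, 0.826% for S/L p20 against S/L p10, 0.00324% for the interaction and 2.51% for p23 against S/L p20. In the tiles of the 5-read minimum, 6 dense tiles were still lower at p23.

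With shares of methylated reads the global difference from S/L was -12.2 for 2i/L p10 and 0.975 for p23, and changed sign to -2.60 for a2i/L, -4.54 for PKCi/L and -1.36 for p30. Intermediate tiles differed by 6.66 at p23 and 8.74 at p30. In 2i/L p20 the differences were -17.0 in tiles of 3 to 9 CpGs, -0.732 in tiles of 10 to 29 and -2.12 in tiles of 30 or more. An intermediate range of 40 to 60% gave 7.02 at p23 and 8.37 at p30.

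Without 1 library each, the share called ran from 0.0227 to 1.15% for 2i/L p20 against 2i/L p10, the highest without 2i/L p20 of J-34. It ran from 0.0518 to 0.126% for S/L p20 against S/L p10, from 0.0194 to 0.346% for the interaction, from 2.77 to 4.69% for a2i/L, from 1.73 to 3.55% for PKCi/L, from 0.622 to 0.868% for p23 and from 1.26 to 2.74% for p30 against S/L p20. It ran from 0.0356 to 0.0971% for PKCi/L against a2i/L and from 0.0971 to 0.139% for p30 against p23. Of the tiles lower in 2i/L p10, 0.172 to 0.888% were lower at p23 and 0.0202 to 0.242% at p30, and 3 to 11 dense tiles were still lower at p23. A group left with 1 library is assumed to vary like the others, and most of these counts fell with the smaller number of libraries.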

Other observations

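The tests of the dense tiles and of the S/L level in this part were chosen only after the results were seen; the correlation test of the p30 library's line was written before its result, and its reads on chromosome Y were looked at afterwards.

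Keratinocyte libraries were compared tile by tile. Of 47152 tiles, both 2i/L keratinocyte libraries lay 30 points or more below the wild-type library at 85 and above it at 75, while the 2 libraries of the pair differed from each other by as much at 87 and 78 tiles. Of the 85 lower tiles, 11 were dense and 4 of those belonged to the 10 still called lower at p23 in ESCs. The others included tiles on chromosome 15 from 92832375 to 92832867, at 9.76% and 10.0% against 46.1% (Wilson 95% interval 36.1 to 56.4%), and on chromosome 3 from 151755666 to 151755960, at 13.04% and 18.4% against 74.5% (65.7 to 81.8%). The 1 dense tile that was higher lies on chromosome 2 from 174110190 to 174110948, with 81.1% and 87.6% in the 2i/L keratinocytes and 42.2% (33.4 to 51.6%) in the wild-type library. No test was made, since there was 1 wild-type library, and these tiles were chosen after their values were seen.

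In a2i/L p20 the 2 lines differed at dense tiles of the group of 7. On chromosome 10, the tile from 12810429 to 12810995 had 8.54% in one library and 38.7% in the other, and the tile on chromosome 11 from 22872010 to 22872993 had 4.10% and 36.8%. The other tiles on chromosome 11 had 17.9% and 48.3% from 11925612 to 11925947, and 9.35% and 40.8% from 11926175 to 11926884. For the tiles on chromosome 2 the lower value is given first, and it need not come from the same library as on chromosomes 10 and 11. They had 32.1% and 48.3% from 157386010 to 157386214, 45.1% and 48.6% from 174124504 to 174124998, and 39.4% and 42.3% from 174125015 to 174125971. In PKCi/L p20 the tile on chromosome 11 from 22872010 to 22872993 had 20.04% and 27.1%.

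The 7 dense tiles at 30 to 70% in wild-type keratinocytes were low at p23, and 5 of them were called lower than S/L p20 at p30 as well. Loss of 1 copy of each tile would lower its reads, but relative reads at p23 were 1.05 times those of S/L p20 (median; range 0.932 to 1.14). A difference between library sets is argued against on average inside coverage set 3, where p30 lay -22.9 points from a2i/L and PKCi/L p20 (range over tiles -31.2 to -15.3, pooled SD between libraries 6.61), though these differ in medium. This rests on PKCi/L and on 1 of the a2i/L libraries, as the SD over the 7 tiles was 10.9 in a2i/L p20 (n = 2). Its other library was low on chromosomes 10 and 11, though not on chromosome 2. On chromosome 11 from 22872010 to 22872993 it had 4.10%, and the p30 libraries had 1.99% and 11.2%. The presence of 2i/L-like cells left in the cultures is argued against, since the other lost dense tiles had regained a median of 107% at p23. Slow regain stays open, since the mean change of 2.06 points between p23 and p30 has a pooled SD between libraries of 5.66; a lasting loss and selection of cells in 2i/L were not tested. For the other 3 tiles a rise of 14.8 points (range 8.99 to 18.1) met the prediction of slow regain, but 0 coverage sets hold both p23 and p30, so set and passage cannot be told apart in either rise.

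By means over CpGs the S/L level at p20 lay -2.46 points from p10, but by shares of methylated reads -1.18 points (exact two-sided permutation p = 0.2), and tiles of 3 to 9 CpGs had 31.2% at p20 and 31.0% at p10 by these shares. Incomplete bisulfite conversion at p10 would have raised nearly unmethylated DNA there; as means over tiles of 30 or more CpGs p20 lay -0.0520 points from p10, which argues against it for the fall in means. By shares of methylated reads these tiles lay -0.970 points apart (exact two-sided permutation p = 0.3), which alone does not decide the question. As means over tiles they had 0.594% ± 0.0153 in S/L p10 and 0.542% ± 0.0245 in S/L p20 (SD, n = 3 each). Incomplete conversion alike at all CpGs could not exceed these means, which argues against it for the shares as well. Failure limited to some CpGs was not tested. Shares of methylated reads can also be moved by CpGs with very many reads, which was not tested here. A difference between library sets may account for the change: 0 coverage sets hold S/L libraries of both passages, so set and passage cannot be told apart. Time in culture stays open as well, untested.

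The p30 library titled J-35 could not be given a line. Its difference from the J-37 library of p30 correlated over tiles with J-34 minus J-35 at p23 at r = 0.0292, which would have to exceed 0.05 for J-34 or lie below -0.05 for J-35. Libraries of known line did not separate on this measure (r from -0.0232 to 0.0459), so that test decides nothing. Its 33.8 reads on chromosome Y in each 1000000 do not decide it either: J-34 had 38.2 in 2i/L p20 and 37.4 at p23 and J-35 had 62.1 and 57.6, but over their other ESC libraries J-34 reached 76.8 (a2i/L p20) and J-35 went down to 23.9 (PKCi/L p20).

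On chromosome 19, the tile from 8326746 to 8326768 was low in coverage set 2, with 7.53% in S/L p20 and 5.76% at p23, and had 54.4% in S/L p10 and 52.6% at p30. On chromosome 10, the tile from 11211899 to 11211974 was low in the ESC libraries of coverage set 3 instead. It had 11.3% in a2i/L p20, 5.88% in PKCi/L p20 and 10.4% at p30. In S/L p10 it had 92.1%, in S/L p20 87.9% and at p23 71.6%.

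The number of reads on chromosome Y in each 1000000 reads over CpGs differed among libraries labelled male. The double knockout had 14.4, near the 10.6 of the female wild-type keratinocytes, with 0.929% of reads on chromosome X. The 2i/L keratinocytes had 21.4 and 22.8. S/L p20 had 63.9 to 66.5, while line J-34 had 38.2 in 2i/L p20 and 37.4 at p23, the p30 library titled J-35 had 33.8, and PKCi/L p20 of J-35 had 23.9.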
